A study of Mus musculus with 9 samples.

How the data were processed

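The authors deposited a table of gene expression and a table that compares LPS + H-CDs with LPS. In the first, expression is in FPKM per the name the authors gave it, that is, fragments scaled to gene length and library size, for 54532 genes in 9 libraries. The second holds, for 21576 genes, a signal per library that the authors had scaled between the 6 libraries, and its mean per group. It also holds a log2 fold change of LPS + H-CDs over LPS and a p-value with its adjusted p, all computed by the authors and named in the deposited headers. The columns of the tables abbreviate the supplement to CD, which was read as H-CDs because no other group of the series remained. Per the submitters' processing notes the genome build was GRCm38 (mm10); the aligner, the counting tool, the normalization and the test are not given in the sources used here. RNA was extracted with TRIzol, messenger RNA was captured on poly-T beads and primed with random hexamers, and the labels do not say whether strands were kept apart. Genes that overlap others, or that share reads with pseudogenes or close relatives, such as the ferritin genes, are therefore less certain.

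The values were checked before use. FPKM multiplied by gene length was a whole multiple of 1 step per library for 100% of values above 0, within a tolerance of 0.01, so whole reads could be recovered from every library. The signal of the comparison table was likewise a whole multiple of 1 step per library and gave the same reads. For LPS + H-CDs replicate 3 in that table the step lay so near 1 that a rounding check alone could not tell scaled from unscaled counts. The authors' adjusted p equalled a Benjamini-Hochberg adjustment over the 13210 genes with a value under 1, and was exactly 1 for the other 8366. FPKM had been divided by an adjusted library size. Against each library's own total the factor was 1.13 to 1.15 in control, 0.928 to 0.935 in LPS and 0.983 to 0.993 in LPS + H-CDs, and its ratio to a TMM factor computed from the recovered reads lay between 0.999 and 1.03. This scaling assumes that most genes do not change, and the directions of small shifts between control and the LPS groups depend on it. Of the gene identifiers, 99.9% were found in GENCODE release M21 and 98.3% of those had the same coordinates. A total of 29847 genes had 0 reads in all libraries. Protein-coding genes took 97.1 to 97.4% of the reads and the 10 highest genes 5.41 to 7.47%. Between replicates the recovered reads scattered more than counting error allows, with a chi-square per degree of freedom of 3.43 to 25.6. Floors for genes with no read cover counting error only, whereas each SD and SE given here includes the spread between replicates.

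Genes with an FPKM of at least 1 in at least 3 of the 9 libraries were tested, 11707 in all. A single limma fit with an intensity trend in the prior variance was made on log2(FPKM + 1) over the 9 libraries, with 6 residual degrees of freedom, and each comparison was adjusted by Benjamini-Hochberg over all tested genes. All tests were 2-sided, and 3 comparisons were made. Fold changes in text are ratios of mean FPKM unless given as log2, and a gene with no read in a group is compared with a floor of 3 reads over that group. Counts of genes changed at least 2-fold instead use the log2(FPKM + 1) scale, which understates the change of genes near 0. With 3 libraries against 3, an exact permutation test of 1 gene cannot go below 0.1, so the adjusted p rests on the variance shared across genes. Camera with a preset correlation of 0.01 tested 28 of 35 gene lists, those with at least 5 tested members, and compares a list with all other genes. Camera with an estimated correlation per list and fry were run beside it. The lists, which hold 756 genes and come from general knowledge of macrophages, LPS and oxidative stress and of other cell types, the comparisons, the thresholds, the rule for named genes and most alternatives were fixed before the data were examined. That rule took 12 genes named for the treatments, the 8 highest and 8 lowest fold changes per comparison, up to 4 genes per list by smallest adjusted p, and 5 genes per direction among those called for both LPS and H-CDs. The highest and lowest were taken among protein-coding genes with an adjusted p under 0.05, a gene symbol, no overlap between groups and a mean of at least 5 FPKM in the higher group. Further members of lists were named as examples after their values were seen.

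The relation between both fold changes was set against 100 simulated LPS + H-CDs groups with the level of LPS and the residual spread of each gene. In a self-test on simulated negative binomial reads, with an assumed spread between replicates and known changes for LPS + H-CDs against LPS, 25.8% of genes changed 1.5-fold were recovered, 88.1% of those changed 2-fold and 98.5% of those changed 4-fold, 6.67% of calls were false, and 0 of 30 lists of unchanged genes were called. In that self-test, changes of 1.5-fold in single genes were often missed. Its genes were drawn independently and the members of unchanged lists at random. The 0 of 30 lists therefore says little about real lists, whose genes may move together. The simulated data held far fewer changed genes, with 150 of 11760 called, against 1826 of 11707 in the real comparison. The adjusted p was therefore stricter there, and these shares may not carry over to the real comparison. The alternatives changed the pseudocount, the filter, the scaling, the trend, the weights, the libraries fitted and the test, which included edgeR and DESeq2 on recovered reads. The columns with group means in the comparison table were not analysed here. Results for some genes are not reported. Work was done in R 4.3.3 with limma 3.58.1, edgeR 4.0.16 and DESeq2 1.42.0, and in Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.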

Results

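Messenger RNA was sequenced from RAW 264.7 cells, a mouse macrophage line grown from an ascites tumour, in 9 libraries. The libraries fell into 3 groups of 3. Control cells were untreated. LPS cells received lipopolysaccharide, a cell wall component of Gram-negative bacteria that activates Toll-like receptor 4, at 1 µg/ml. LPS + H-CDs cells received the same LPS together with H-CDs at 400 µg/ml. The design text gives an exposure of 6 h. H-CDs is the submitters' name for the supplement, which the labels do not spell out; the title of the series concerns a nanozyme made from fruit that acts as a superoxide dismutase. Between 14377161 and 16069968 reads per library were recovered from the FPKM values. Between 11020 and 11178 genes per library reached an FPKM of 1. The labels do not say that the 3 libraries of a group came from separate cultures, so all p-values measure only the spread between these samples, which may be technical.

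The first principal component held 74.1% of the variance and parted the control libraries from the 6 libraries with LPS. The second held 9.27% and parted LPS from LPS + H-CDs. Pearson correlations between libraries of one group, across the 11707 tested genes, lay between 0.979 and 0.989; these are correlations across genes, which are not independent replicates. LPS + H-CDs replicate 1 stood apart from its group. The chi-square per degree of freedom between its recovered reads and those of replicates 2 and 3 was 23.9 and 25.6, against 4.99 between replicates 2 and 3, and its score on the second component was -24.3, against -15.8 and -12.4. The 13 messenger RNAs of the mitochondrial genome took 0.490% of its reads, against 1.62% and 1.64% in replicates 2 and 3 and 1.52 ± 0.103% (SD, n = 3) with LPS alone.

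**Figure D1:**
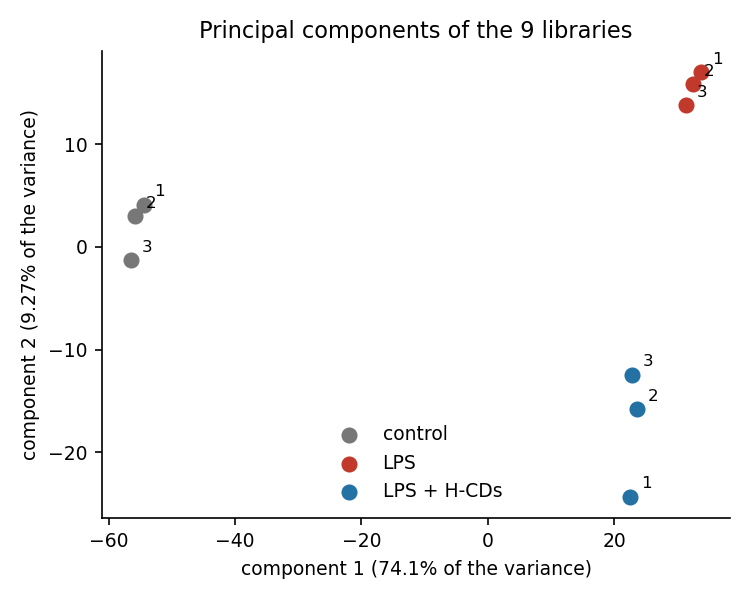
Scores of the 9 libraries on the first 2 principal components of log2(FPKM + 1), with the share of the variance on each axis and the replicate number beside each point. Control libraries lie at the negative end of component 1, and LPS and LPS + H-CDs libraries lie on opposite sides of 0 on component 2.

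The comparison of LPS with control shows the response of the cells to LPS and checks the labels. Inflammatory genes rose by up to several orders of magnitude on the FPKM scale. Il1b, which encodes the cytokine interleukin-1 beta, rose from 0.0612 ± 0.0628 to 460.1 ± 6.14 FPKM (SD, n = 3 per group here and below). Tnf, encoding tumour necrosis factor, rose 46.4-fold, from 57.8 ± 2.05 to 2684 ± 70.8 FPKM. Nos2, the inducible nitric oxide synthase, rose 89.8-fold to 129 ± 17.0 FPKM, and Ptgs2, the inducible cyclooxygenase, rose 736-fold to 1721 ± 189 FPKM. Il6 had no read in any control library and reached 16.5 ± 1.19 FPKM with LPS, at least 699-fold higher against a floor of 3 reads over the control group. The limma adjusted p was 3.41e-12 for Il1b, 5.06e-10 for Tnf, 2.99e-09 for Nos2, 2.04e-11 for Ptgs2 and 3.34e-09 for Il6.

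By the rule for named genes, which asks for a mean of at least 5 FPKM in the higher group, the highest fold changes past the threshold on the log2(FPKM + 1) scale belonged to Csf3, encoding granulocyte colony-stimulating factor (log2 fold change 10.30 ± 0.09, SE), the chemokine gene Cxcl2 (9.61 ± 0.11), Acod1, whose enzyme makes itaconate (9.53 ± 0.07), Ptgs2 (9.01 ± 0.11), Ccl5 (9.002 ± 0.20), Il1b (8.76 ± 0.07), Il27 (7.73 ± 0.09) and Ccl3 (7.65 ± 0.21). The lowest belonged to Kbtbd11, which fell from 73.9 ± 4.29 to 4.05 ± 0.351 FPKM (log2 fold change -3.89 ± 0.07), Susd3 (-3.05), Ranbp3l (-2.87), the constitutive cyclooxygenase gene Ptgs1 (-2.87), Cldn11 (-2.68), Slc43a2 (-2.60), Shtn1 (-2.56) and Plekhg5 (-2.54). The adjusted p of these genes in limma was at most 9.33e-08. Fold changes are on the log2(FPKM + 1) scale, which understates the change of genes near 0.

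By gene list, all 13 tested genes of the proinflammatory cytokine list were higher with LPS, with a median log2 fold change of 5.51 (camera adjusted p = 9.91e-13, and 0.0443 with an estimated correlation). All 11 tested chemokine genes were higher, among them Ccl4, Cxcl10 and Ccl22 (camera adjusted p = 2.97e-11, but adjusted p = 0.0576 with an estimated correlation). Of 38 interferon-stimulated genes, 37 were higher, among them Oasl1 (9.40 to 362 FPKM), Irf7 (4.16 to 98.8 FPKM), Ifit3 and Usp18 (camera adjusted p = 1.68e-24). All 22 genes of the NF-kB pathway and its feedback rose, with Tnfaip3, Traf1, Zc3h12a and Ikbke lowest in p (camera adjusted p = 7.59e-17), as did all 18 inducible macrophage effector genes (camera adjusted p = 2.76e-14) and all 10 anti-inflammatory mediators, such as Socs3, Zfp36 and Il1rn (camera adjusted p = 4.45e-08). Of 24 immediate early and MAPK feedback genes, 23 rose (camera adjusted p = 2.02e-13). All of these lists but the chemokines kept their call with an estimated correlation, and the counts were the same when adjusted over the list alone, except that 24 immediate early genes then passed.

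Proliferation genes moved the other way: 32 of 36 cell cycle genes fell and 2 rose, both over all genes and when adjusted over the list alone, with a median log2 fold change of -0.71 (camera adjusted p = 1.14e-11, and 0.00229 with an estimated correlation). Thymidine kinase Tk1 fell from 41.6 ± 2.08 to 7.10 ± 0.233 FPKM, and the replication licensing gene Cdc6 from 14.97 ± 0.275 to 4.43 ± 0.157 FPKM. The integrated stress response list had 24 higher, 4 lower and 1 not past the threshold (camera adjusted p = 2.48e-06, adjusted p = 0.0807 with an estimated correlation). The camera calls of 4 smaller shifts likewise ended with an estimated correlation. These were the heat shock list (11 higher, 1 lower of 14; adjusted p = 0.00901 and 0.0885 with an estimated correlation), antigen presentation (12 higher, 1 lower of 18; 0.00101 and 0.221), Toll-like receptor 4 signalling (15 higher, 5 lower of 27; 0.0492 and 0.454) and nuclear respiratory chain subunits (1 higher, 10 lower of 37; 0.0267 and 0.698).

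Antioxidant genes went both ways with LPS. Sod2, the mitochondrial manganese superoxide dismutase, rose 5.56-fold, from 11.4 ± 0.238 to 63.4 ± 3.68 FPKM (limma adjusted p = 2.31e-09). Catalase (Cat), which breaks down hydrogen peroxide, fell from 34.3 ± 0.893 to 17.2 ± 0.969 FPKM (adjusted p = 9.49e-05), and the glutathione peroxidase gene Gpx1 fell from 202 ± 8.86 to 93.8 ± 5.74 FPKM (adjusted p = 1.60e-06). Of 20 superoxide and peroxide detoxifying enzymes, 6 rose and 8 fell (median log2 fold change -0.08, mean 0.13, camera downward with adjusted p = 0.712). The 26 tested targets of NRF2, the transcription factor of the oxidative stress response, had 10 higher, 14 lower and 2 not past the threshold (camera adjusted p = 0.375). The heme oxygenase gene Hmox1 had a log2 fold change of 0.23 ± 0.07 (limma adjusted p = 0.0247) and the cytosolic superoxide dismutase gene Sod1 of -0.37 ± 0.11 (adjusted p = 0.0197); both calls ended under some alternative settings, and for Hmox1 the sign turned when libraries were rescaled to TPM (-0.12) or to their total reads (-0.06).

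In total, 6508 of 11707 tested genes passed an adjusted p of 0.05 in limma, 3372 higher and 3136 lower with LPS, and 844 and 539 of them changed at least 2-fold. The libraries of both groups did not overlap in 63.9% of the tested genes, where chance gives 10%. The balance of directions depended on the scale between libraries: rescaled to TPM, 1676 genes were higher and 5657 lower, and scaled to total reads 1904 and 5191. These scales moved the median log2 fold change of all tested genes from 0.03 to -0.30 and -0.22.

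The comparison of LPS + H-CDs with LPS addresses what H-CDs changed in cells under LPS. By the rule for named genes, which asks for a mean of at least 5 FPKM in the higher group, the highest call on the log2(FPKM + 1) scale was Hmox1 (ENSMUSG00000005413, chromosome 8, 75093621 to 75100589, GRCm38), whose enzyme breaks down heme: it rose 24.1-fold, from 86.1 ± 3.30 to 2074 ± 54.9 FPKM (log2 fold change 4.57 ± 0.07, SE; limma adjusted p = 2.51e-09). Srxn1 (ENSMUSG00000032802, chromosome 2, 152105516 to 152111376), encoding sulfiredoxin, which repairs oxidised peroxiredoxins, rose 9.65-fold to 148 ± 3.24 FPKM, and Gclm (ENSMUSG00000028124, chromosome 3, 122245557 to 122270732), a subunit of the enzyme that starts glutathione synthesis, rose 9.95-fold to 82.3 ± 3.06 FPKM. At the other end, the chemokine gene Ccl22 (ENSMUSG00000031779, chromosome 8, 94745590 to 94751699) fell from 157 ± 12.6 to 29.2 ± 2.52 FPKM (5.37-fold; adjusted p = 6.37e-07), and the acute phase gene Saa3 (ENSMUSG00000040026, chromosome 7, 46711998 to 46715700) from 39.6 ± 5.09 to 6.99 ± 1.18 FPKM (5.67-fold; adjusted p = 2.24e-05). In each of these 5 genes all libraries of one group lay above all libraries of the other, which the rule for named genes required.

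The next highest were the heme transporter gene Slc48a1 (log2 fold change 2.85 ± 0.12), Procr, the protein C receptor (2.77 ± 0.08), the aldo-keto reductase gene Akr1b8 (2.65 ± 0.06), Prdx1, encoding peroxiredoxin 1 (2.38 ± 0.10), and Layn (2.34 ± 0.08). The next lowest were Il1rn, the interleukin-1 receptor antagonist (-2.09 ± 0.12), the macrophage lectin gene Siglec1 (-2.01 ± 0.09), Ccl17 (-1.85 ± 0.20), Wfdc17 (-1.83 ± 0.19), the receptor tyrosine kinase gene Axl (-1.81 ± 0.11) and Lcn2, encoding the iron-siderophore binding protein lipocalin 2 (-1.73 ± 0.11). Their limma adjusted p lay between 3.17e-08 and 4.16e-04.

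Cytokine and enzyme genes fixed before the data were examined differed in how far they moved. Il1b fell from 460.1 ± 6.14 to 237 ± 19.8 FPKM (1.94-fold, limma adjusted p = 6.17e-05), Nos2 from 129 ± 17.0 to 51.5 ± 0.163 FPKM (2.50-fold, adjusted p = 7.18e-04) and Il6 from 16.5 ± 1.19 to 10.2 ± 1.81 FPKM (1.62-fold, adjusted p = 0.00500). Tnf was at 2684 ± 70.8 and 2559 ± 435 FPKM (adjusted p = 0.680) and Ptgs2 at 1721 ± 189 and 1527 ± 175 FPKM (adjusted p = 0.351), differences within the spread between replicates; for Tnf the sign turned under 3 alternative settings, with values up to 0.06. Cat rose 3.003-fold, from 17.2 ± 0.969 to 51.7 ± 9.21 FPKM (adjusted p = 6.50e-05). Sod2 fell from 63.4 ± 3.68 to 46.8 ± 2.13 FPKM (adjusted p = 0.00193), and Sod1 was at 49.4 ± 4.72 and 69.2 ± 6.79 FPKM (adjusted p = 0.0210), a call that ended without LPS replicate 1 or 2, without LPS + H-CDs replicate 1 or 2, and with no filter on low values. Of the remaining fixed genes, Nqo1, Il10 and Sod3 stayed under the filter on low values and were not in the fit. Nqo1 had 3, 1 and 2 reads in the LPS libraries and 12, 11 and 12 in the LPS + H-CDs libraries, Il10 had 5, 21 and 10 and 3, 11 and 9, and Sod3 had none in any library.

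**Figure D2:**
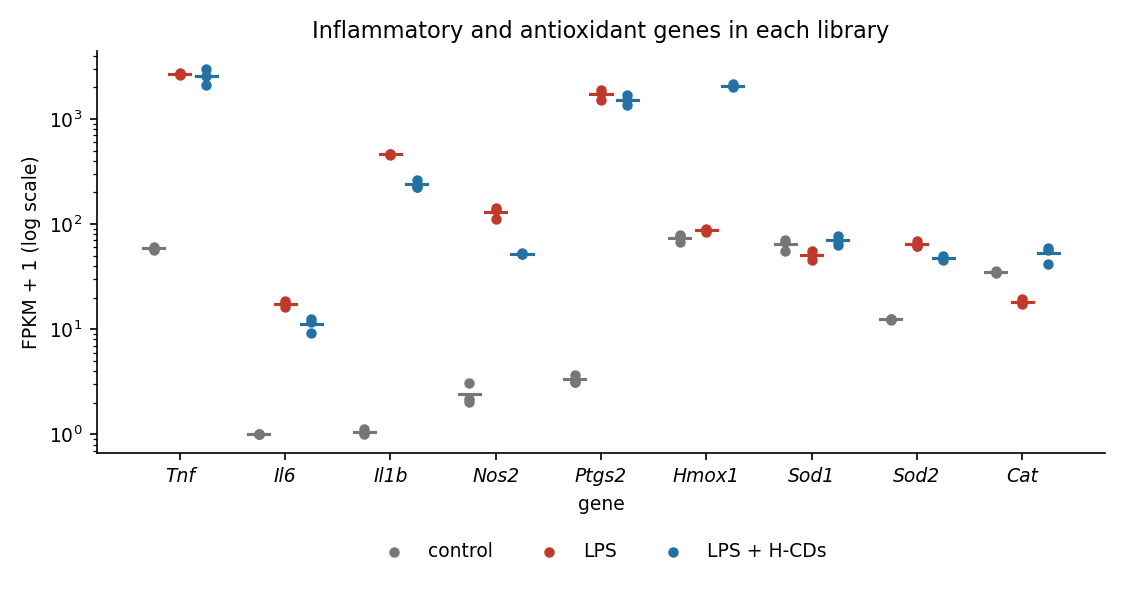
FPKM + 1 on a log axis for the 9 tested genes of the set fixed beforehand, 1 point per library and a bar at the group mean. Hmox1 stands near 2074 FPKM in the LPS + H-CDs libraries against 86.1 FPKM with LPS alone, and Il1b, Nos2 and Il6 stand between their control and LPS levels.

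NRF2 targets moved together. Of 26 tested, 21 rose with H-CDs, none fell and 5 did not pass, with 22 higher and 0 lower when adjusted over the list alone, and the median log2 fold change was 1.24 (camera adjusted p = 8.88e-31, and 0.00501 with an estimated correlation). Besides those named above they included the cystine transporter gene Slc7a11 (17.3 to 69.6 FPKM), Sqstm1, an autophagy receptor (220.3 to 937 FPKM), Gclc, the catalytic partner of Gclm (14.8 to 32.4 FPKM), and Txnrd1, a thioredoxin reductase (86.8 to 214 FPKM). The superoxide and peroxide detoxifying enzymes as a list had 6 higher, 3 lower and 11 not past the threshold (camera adjusted p = 0.0649). The integrated stress response list, which shares Slc7a11 with the NRF2 list, had 20 higher, 0 lower and 9 not past the threshold (camera adjusted p = 2.74e-13, and 0.0222 with an estimated correlation), with the amino acid genes Slc3a2, Asns (105 to 169.6 FPKM) and Pck2 among them. Endoplasmic reticulum chaperone and unfolded protein response genes had 9 higher, 0 lower and 14 not past the threshold (camera adjusted p = 9.67e-07, and 0.0281 with an estimated correlation), such as Pdia4, Dnajc3 and Hspa5 (902 to 1273 FPKM). When adjusted over the list alone, 21 genes of the integrated stress response list and 11 of the chaperone list were higher.

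Many genes raised by LPS were lower with H-CDs. Of 13 proinflammatory cytokine genes 10 fell, with the smallest p for Csf2 (131 to 46.6 FPKM), Il27 (311 to 107 FPKM), Il1b and Csf3, while the interleukin-23 subunit gene Il23a rose (log2 fold change 0.56) and Tnf and Osm did not pass (camera adjusted p = 9.67e-07, but adjusted p = 0.124 with an estimated correlation). Of 11 chemokine genes 7 fell, among them Ccl22, Ccl2 (36.3 to 11.4 FPKM), Ccl17 and Cxcl16, and Cxcl2 rose from 1183 ± 64.2 to 1886 ± 329.5 FPKM (camera adjusted p = 3.55e-05, but adjusted p = 0.169 with an estimated correlation). The next 3 lists kept their camera call with an estimated correlation. The 38 tested interferon-stimulated genes had 0 higher, 25 lower and 13 not past the threshold, with Ifit3, Zbp1, Ifi204 and Gbp3 lowest in p (camera adjusted p = 1.52e-14, and 0.00725 with an estimated correlation). The NF-kB list of 22 tested genes had 0 higher, 14 lower and 8 not past the threshold (4.27e-11 and 0.00789), with the feedback gene Tnfaip3 falling from 47.9 ± 1.94 to 20.2 ± 0.484 FPKM. The 18 inducible effector genes had 1 higher, 14 lower and 3 not past the threshold (1.87e-10 and 0.00517), with the co-stimulatory receptor gene Cd40 at 52.2 and 24.3 FPKM and Edn1, encoding endothelin-1, at 25.5 and 7.52 FPKM.

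Adjusted over the list alone, 10 cytokine, 7 chemokine, 29 interferon-stimulated, 15 NF-kB and 14 effector genes were lower, and 1, 1, 1, 0 and 1 were higher in the same order. The anti-inflammatory mediators also fell, 7 of 10 with no gene higher, both over all genes and when adjusted over the list alone, with Il1rn, Bcl3, Zfp36, which destabilises cytokine messenger RNAs, and Socs3 among them (camera adjusted p = 4.67e-05, but adjusted p = 0.0841 with an estimated correlation). Immediate early and MAPK feedback genes had 2 higher, 11 lower and 11 not past the threshold (camera adjusted p = 0.0315, but adjusted p = 0.257 with an estimated correlation); Myc and Egr1 fell, and Atf3 and Ier3 rose by log2 0.75 and 0.68. Without LPS + H-CDs replicate 1, 22 NRF2 targets rose, and 10 cytokine, 7 chemokine, 24 interferon-stimulated, 14 NF-kB and 13 effector genes fell. The 13 mitochondrially encoded messenger RNAs, which were low in that library, had a median log2 fold change of -0.55 with all libraries and 0.03 without it, with no gene past the threshold either way (camera adjusted p = 0.144 and 0.316).

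**Figure D3:**
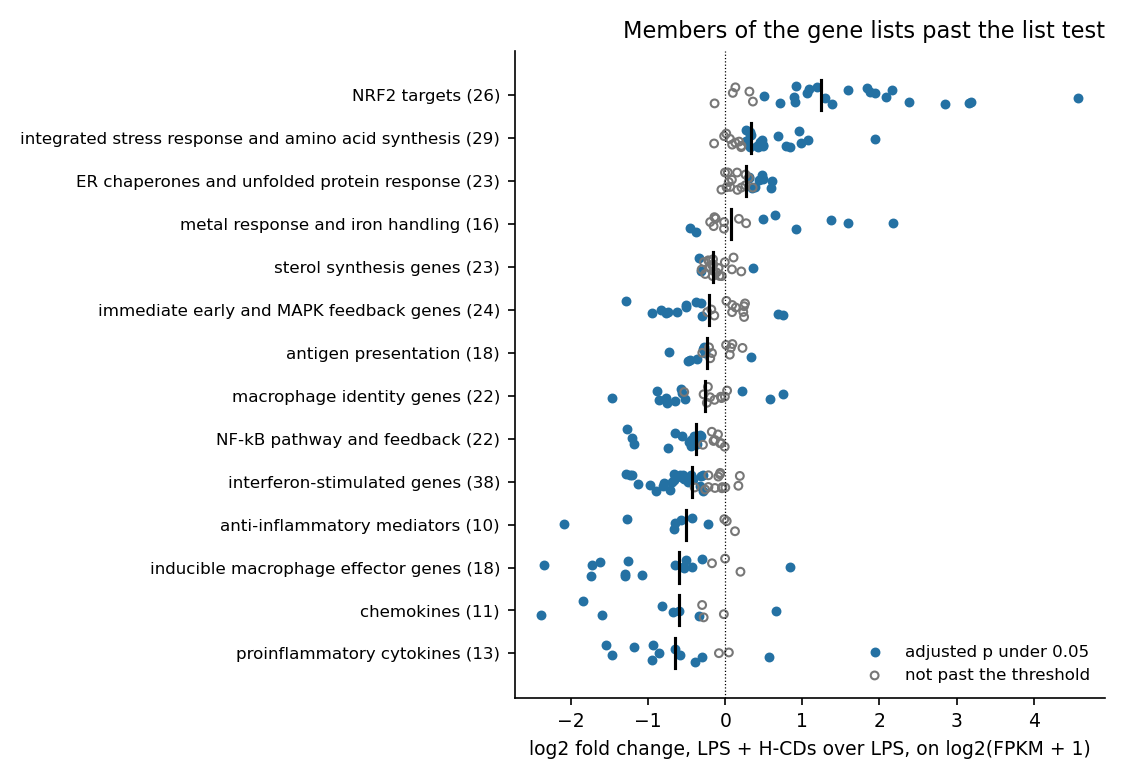
Log2 fold change of LPS + H-CDs over LPS on the log2(FPKM + 1) scale for each tested member of the 14 gene lists past the camera threshold, with the number of tested genes in brackets, filled points for genes past an adjusted p of 0.05 and a bar at the list median. The medians run from -0.65 for proinflammatory cytokines to 1.24 for NRF2 targets.

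In total, 1826 of 11707 tested genes passed, 766 higher and 1060 lower with H-CDs. On the log2(FPKM + 1) scale 55 and 79 of them changed at least 2-fold. The groups did not overlap in 36.8% of tested genes, where chance gives 10%. The authors' deposited table called 2184 of 21576 genes at an adjusted p of 0.05, 889 higher and 1295 lower. Of these, 139 higher and 150 lower genes changed at least 2-fold by the authors' own log2 fold change. Both tests called 1616 genes, all with the same sign, but they rest on the same reads of the same libraries. Their agreement is therefore not independent support. In the authors' deposited table the log2 fold change was 4.61 for Hmox1, -0.94 for Il1b, -2.41 for Ccl22 and -0.05 for Tnf. The number of calls was 1098 without LPS replicate 1, 1022 without LPS replicate 2, 1185 without LPS + H-CDs replicate 2, 1498 without LPS + H-CDs replicate 1 and 3352 with library quality weights. Rescaled to TPM, 875 genes were higher and 690 lower, and scaled to total reads 1195 and 690.

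Genes that LPS raised tended to be lower with H-CDs. Of 3372 genes raised by LPS, 788 fell with H-CDs and 168 rose further, where independent lists would share 305 and 221. Of 3136 genes lowered by LPS, 398 rose and 85 fell further, against 205 and 284. Independent lists leave out that both comparisons share the LPS libraries. With the sharing but an unchanged LPS + H-CDs group, none of these 4 counts exceeded 2 in 100 simulations, which leave out the effects of H-CDs. The 3 LPS libraries cannot be split into parts of at least 2, so part of the excess of these counts may come from the shared libraries. Genes raised by LPS and lowered by H-CDs included Ccl22, Csf2, Siglec1, Tnfaip3 and Cd40. Genes lowered by LPS and raised by H-CDs included Ank, a pyrophosphate transporter gene (97.7, 48.8 and 103 FPKM in control, LPS and LPS + H-CDs), Gclc, Slc48a1, the lysosomal lipase gene Lipa (95.9, 40.6 and 84.8 FPKM) and Osgin1. Procr, Sqstm1, Slc7a11, Txnrd1 and Asns rose in both comparisons. The potassium channel gene Kcnn4, Gpx1, cyclin D1 (Ccnd1), lysozyme (Lyz2; 1624, 897 and 495 FPKM) and Nfam1 fell in both.

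Both fold changes use the same LPS libraries, with opposite signs, so opposite directions arise with no effect of H-CDs. Among genes called for LPS, 70.2% had an H-CDs fold change of the opposite sign, against 53.4 to 56.8% in 100 simulations of an unchanged LPS + H-CDs group. The covariance of the fold changes across genes was -0.110, against a simulated mean of -0.0118, a difference of -0.0978. Pearson's r across genes, which are not independent replicates, was -0.417, against a simulated mean of -0.0922 (range -0.115 to -0.0650).

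**Figure D4:**
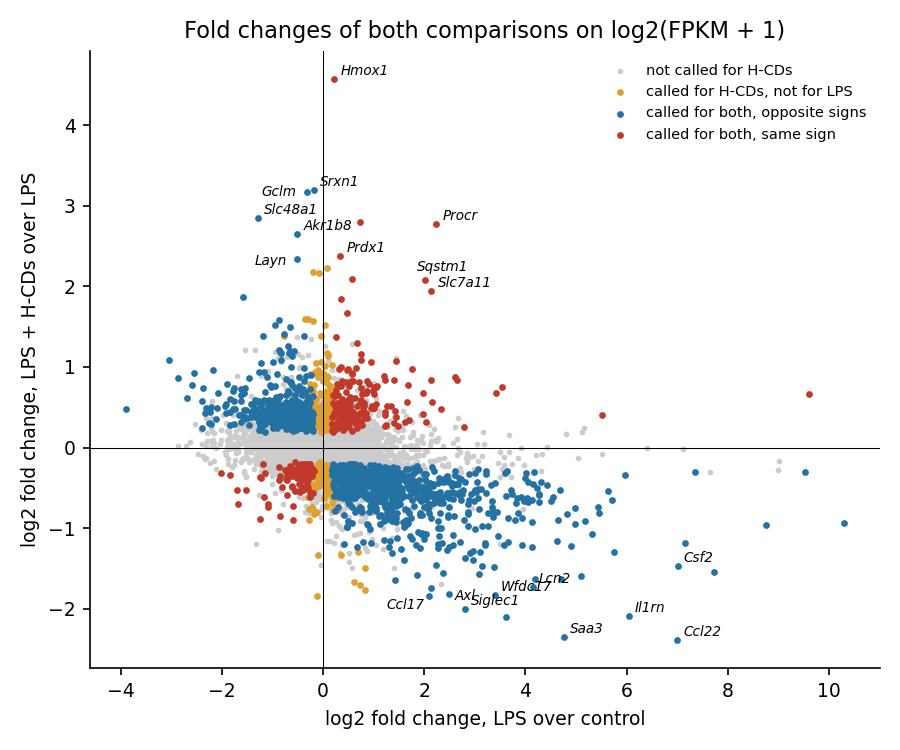
Log2 fold change of LPS over control (horizontal axis) and of LPS + H-CDs over LPS (vertical axis) on the log2(FPKM + 1) scale, 1 point per tested gene, grey where not called for H-CDs, orange where called for H-CDs alone, and blue or red where called for both with opposite or equal signs. Strongly induced genes such as Ccl22, Il1rn and Saa3 lie below 0 on the vertical axis, and Hmox1, Srxn1 and Gclm lie near 0 on the horizontal axis.

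The comparison of LPS + H-CDs with control shows how far cells given both treatments stood from untreated cells. The highest genes, chosen by the same rule, were again genes raised by LPS. Cxcl2 was higher than in control by log2 10.27 ± 0.11 (SE), Csf3 by 9.36 ± 0.09, Acod1 by 9.23 ± 0.07, Ptgs2 by 8.84 ± 0.11, Ccl5 by 8.72 ± 0.20, Il1b by 7.81 ± 0.07, Ccl3 by 7.35 ± 0.21 and Ccl4 by 7.10 ± 0.07. Hmox1 stood 28.2-fold above control (limma adjusted p = 9.40e-11). Il6, with no read in control, was at least 432-fold higher against the same floor. Cat, at 51.7 ± 9.21 against 34.3 ± 0.893 FPKM, was also higher (adjusted p = 0.00299, ending when libraries were rescaled to TPM), and Sod1, whose sign turned when libraries were rescaled to TPM (-0.20), did not pass (adjusted p = 0.450). The lowest genes were Kbtbd11 (-3.41), Ranbp3l (-2.85), Lrrc75a (-2.56), the cholesterol exporter gene Abcg1 (-2.48), Chst1 (-2.45), Lyl1 (-2.42), Myo1f (-2.39) and Ahnak (-2.38), in log2 fold change.

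All 13 cytokine genes, 10 of 11 chemokine genes and 37 of 38 interferon-stimulated genes were above control (camera adjusted p = 5.84e-13, 1.59e-10 and 9.03e-24; adjusted p = 0.0325, 0.0541 and 0.00198 with an estimated correlation). The same held for 21 of 22 NF-kB genes, 17 of 18 effector genes, all 10 anti-inflammatory mediators and 22 of 24 immediate early genes (camera adjusted p = 1.22e-16, 1.25e-12, 4.42e-08 and 5.31e-12; adjusted p = 0.00240, 0.00198, 0.0264 and 0.0171 with an estimated correlation). NRF2 targets had 18 higher, 3 lower and 5 not past the threshold, and 20 higher and 3 lower when adjusted over the list alone (camera adjusted p = 7.49e-08, and 0.0298 with an estimated correlation). Integrated stress response genes had 25 higher, 0 lower and 4 not past the threshold (adjusted p = 7.27e-12, and 0.0264 with an estimated correlation), and 32 of 36 cell cycle genes were lower (3.59e-14 and 0.00198). The counts of the other lists named here were the same when adjusted over the list alone. In total, 6090 genes passed, 3120 higher and 2970 lower, 713 and 458 of them by at least 2-fold, and the groups did not overlap in 57.7% of tested genes (10% by chance). Rescaled to TPM the split was 1651 higher and 5338 lower, and scaled to total reads 2033 and 4528, with the median log2 fold change of all genes moving from 0.01 to -0.28 and -0.16.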

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

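Scaling to total reads, protein-coding genes only, edgeR on all 9 libraries and the list tests without LPS + H-CDs replicate 1 were chosen after seeing the data. For single genes, 2573 alternative values kept direction and side of the threshold, 16 lost the threshold and 7 changed sign. These belong to 106 results of genes named by the rule, mainly ones with large fold changes or small p, so they say little about other genes. Of the 1826 genes called for H-CDs, 1007 (without LPS replicate 2) to 1653 (without control replicate 1) were also called when 1 library was left out. Of the 6508 called for LPS, 4826 were also called when rescaled to TPM. For Hmox1, LPS against control gave a log2 fold change of -0.120 rescaled to TPM and -0.0605 scaled to total reads. Sod1, LPS + H-CDs against control, gave -0.198 and -0.0956. Tnf, LPS + H-CDs against LPS, gave 0.0531 with quantile normalization, 0.0580 with quality weights and 0.0470 without LPS + H-CDs replicate 1, the highest of -0.201 to 0.0470 when 1 library was left out. Both rescalings put the control libraries on a different scale by construction; for Tnf the cause was not tested. With at least 2-fold required, 1383, 134 and 1171 genes passed for LPS against control, LPS + H-CDs against LPS and LPS + H-CDs against control, a stricter rule by construction. Leaving out 1 library gave 5736 to 6788, 1022 to 1760 and 5370 to 5919 genes in the same order. Library quality weights gave 3352 genes for H-CDs, and the cause was not tested. On recovered reads, edgeR gave 2295 and DESeq2 2184 genes for H-CDs. The DESeq2 count and its split, 889 higher and 1295 lower, equalled those of the authors' deposited table. These 2 results therefore do not count as separate support. An estimated correlation left 7, 6 and 9 lists of 13, 14 and 17. Fry, which does not compare a list with other genes, called 24 for LPS against control and turned the direction of superoxide and peroxide detoxifying enzymes (adjusted p = 0.0122), macrophage identity genes (0.0224) and osteoclast-like differentiation (9.38e-04). Nqo1, Il10 and Sod3 stayed under the filter on FPKM.

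The replicate numbers gave no clear sign of paired libraries, since 4 of 9 libraries correlated best with their own number. Residual correlations of libraries with the same number ran from -0.121 to 0.198, and of those with other numbers from -0.166 to 0.168. With 3 libraries per group this cannot show that pairing was absent. With a replicate block, 6276, 1485 and 5836 genes and 12, 15 and 17 lists passed, the share of opposite signs was 70.6% and the covariance -0.110. The list of NADPH oxidase and ROS-producing enzymes was then called for H-CDs (camera adjusted p = 0.0444; without the block, adjusted p = 0.201 with an estimated correlation).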

Other observations

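Other gene lists also moved between LPS + H-CDs and LPS. Of 16 metal response and iron handling genes, 6 rose and 2 fell, or 7 and 2 when adjusted over the list alone (camera adjusted p = 0.0166, but adjusted p = 0.0935 with an estimated correlation). This list shares the ferritin genes Fth1 and Ftl1 with the NRF2 list, so the results of these lists are not independent. The iron exporter gene Slc40a1 rose from 0.0949 ± 0.0403 to 3.94 ± 0.295 FPKM (SD, n = 3), Ftl1, the ferritin light chain, from 549 ± 3.05 to 1658 ± 74.3 FPKM and the phagosomal metal transporter gene Slc11a1 from 16.4 ± 0.527 to 44.0 ± 3.12 FPKM; Ftl1 has pseudogenes in the table, so its reads are uncertain. The 22 macrophage identity genes had 3 higher, 9 lower and 10 not past the threshold, and 3 higher and 13 lower when adjusted over the list alone (camera adjusted p = 1.83e-04, but adjusted p = 0.129 with an estimated correlation). The scavenger receptor gene Msr1 fell from 46.9 ± 1.92 to 16.3 ± 2.07 FPKM and Fcgr1, an immunoglobulin receptor gene, from 34.8 ± 1.18 to 20.1 ± 2.35 FPKM, whereas the lipid receptor gene Trem2 rose by log2 0.58. Antigen presentation genes had 1 higher, 8 lower and 9 not past the threshold (camera adjusted p = 0.0291, but adjusted p = 0.321 with an estimated correlation), and 5 lower without LPS + H-CDs replicate 1, with Nlrc5, a regulator of MHC class I genes, lowest at log2 -0.73. Of 23 sterol synthesis genes, Ebp was higher and Srebf2 and Hmgcs1 were lower, or 1 higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.0291, but adjusted p = 0.103 with an estimated correlation).

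Within lists that camera did not call as a whole with all libraries, single genes changed. Cybb, the catalytic subunit of the phagocyte NADPH oxidase, fell by log2 0.60 (list camera adjusted p = 0.05005). Without LPS + H-CDs replicate 1, camera called the NADPH oxidase list (adjusted p = 0.0413) and the cell cycle list (adjusted p = 0.0461). With all libraries these had adjusted p = 0.201 and adjusted p = 0.169 with an estimated correlation. Casp1, the inflammasome protease gene, rose by log2 0.71 and Ninj1, needed for plasma membrane rupture, by 0.94, while Casp4 fell by 0.57 (inflammasome list camera adjusted p = 0.730). The metalloproteinase gene Mmp9 fell from 9.31 ± 0.600 to 3.18 ± 0.311 FPKM. Its list, osteoclast-like differentiation, had 1 higher and 3 lower of 5 (camera adjusted p = 0.0991). The glycolysis regulator gene Pfkfb3 fell from 35.9 ± 3.99 to 15.96 ± 0.702 FPKM. More genes of its list, glycolysis and HIF targets, rose than fell, with 6 higher and 2 lower of 31 (camera adjusted p = 0.117). None of 37 nuclear respiratory chain genes passed. The highest marker of another cell type was Ighm at 85.3, 63.3 and 49.2 FPKM in control, LPS and LPS + H-CDs, followed by Lck at 1.13, 4.07 and 4.43 FPKM. The fibroblast, neutrophil and epithelial markers stayed under the filter on low values.

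The tests of a weaker LPS response were chosen after the result was seen, and the predictions of all others were written before they were run. Higher NRF2 targets with H-CDs were weighed against a single unusual library and against reads shared with pseudogenes. Without LPS + H-CDs replicate 1 the median log2 fold change of the list was 1.20, against 1.24 with it, so that library does not account for the rise. Over the 24 members with no pseudogene named after them the median was 1.14. Only 2 members were left out, too few to move a median far, and pseudogenes under other names were not counted. Shared reads were therefore not excluded. An action of H-CDs on NRF2 or on the supply of heme, iron or oxidants remains a hypothesis that was not tested. In addition, no library analysed here held H-CDs without LPS.

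Fold changes of opposite sign for LPS and H-CDs were weighed against the shared LPS libraries and against a weaker LPS response. The covariance of -0.110 lay below the whole simulated range, -0.0149 to -0.00824, so the shared libraries account for only part of it. An equal weakening of every raised gene left a chi-square per degree of freedom of 40.4 over 301 genes raised at least 4-fold, far more scatter than their errors allow. A weakening that differs by gene remains open for the 202 of these genes called lower with H-CDs. It does not by itself account for the 14 (4.65%) called higher, such as Procr (log2 fold change 2.77). The bound for that share was set after the result was seen, and a weakening free to differ by gene allows almost any set of falls. This test therefore decides little. Less LPS reaching the cells and an action of H-CDs inside them may both lower raised genes, and no test here separates them.

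Low mitochondrial transcripts in LPS + H-CDs replicate 1 were weighed against bias by GC content or length and against an effect of H-CDs. The 13 mitochondrial messenger RNAs deviated by a median log2 of -1.69 in that library, whereas 538 nuclear genes of matched GC content deviated by -0.00779 and 825 of matched length by 0.0661, so neither bias fits. Replicates 2 and 3 both lay above the lowest LPS library, the lower of them by log2 0.42, so no fall common to the H-CDs group was seen. How that library was handled, for example which fragments were captured, could differ, and this was not tested.

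Regrouping the 6 libraries of a comparison allows 10 splits, too few for a share under 0.05. The true groups gave 6508 genes for LPS against control, 1826 for LPS + H-CDs against LPS and 6090 for LPS + H-CDs against control, and the highest other split gave 1, 0 and 0, so that 1 of 10 splits reached the true count each time. Every other split mixes libraries of both groups, so a difference between the groups widens its spread and lowers its count. The low counts of the other splits therefore do not show what chance alone would give.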
